A study of Mus musculus with 8 samples.

How the data were processed

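Single-nucleus RNA was counted in 8 libraries of mouse hippocampus, 1 library per animal, from 4 groups of 2 libraries. The groups combined an age, postnatal day 31 (P31) or 192 (P192), with a genotype. Control mice carried floxed Bace1 alleles (Bace1-fl/fl), and cre mice carried the same alleles with a Thy1-cre transgene (Bace1-fl/fl;Thy1-cre), which drives Cre recombinase in neurons. Each group held 1 male and 1 female. Replicate 1 was the male at P192 and the female at P31. The replicate numbers pair animals of the same age and sex, not the same animal, and no litter or preparation day was used here. In the labels the P192 libraries come before the P31 libraries.

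Per the labels' protocols, nuclei were captured in droplets with 10x Chromium reagents, sequenced on a NovaSeq instrument, aligned with STAR and counted with Cell Ranger. The Cell Ranger version is 3.1.0 per the labels' protocols, 6.0.1 per the file headers and 7.0.0 per the submitters' processing notes, and the genome is mm10. The deposited matrices hold raw UMI counts per gene and nucleus, with no normalization by the authors. The submitters' processing notes name Seurat and a filter of under 5% mitochondrial counts and 250 to 6000 detected genes. The deposited matrices still hold the nuclei that this filter would remove, so it was applied here. Of 32285 gene identifiers in the files, 32235 were found in GENCODE vM21, which gave positions on GRCm38 (mm10).

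The 8 libraries held 7061 to 9507 barcodes and 41166883 to 55869785 UMIs each, with 69327 barcodes in all. The mitochondrial limit removed 1365 nuclei and the gene limits removed 288. Scrublet, run in scanpy 1.11.5 with an expected doublet rate proportional to the number of nuclei, called 2147 doublets, which were removed. Counts were scaled to 10000 per nucleus and logged. Then 2000 variable genes, 40 principal components, 20 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, seed 1) gave 38 clusters, with no integration of libraries.

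Clusters were named from 22 lists holding 158 marker genes, fixed before the data were examined together with the gene lists, the designs, the tests, the alternative settings and the rule for naming genes. A name needed a marker score of at least 0.5 and at least 3 markers detected in 10% of nuclei. Names carry "-like" because the labels give no cell types. A cluster also stayed unnamed where its 10 leading genes held more markers of another class than of its own, or where its nuclei had few UMIs and no marker of its own led. Clusters without a name were kept in the total of nuclei and were not tested for expression.

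Counts were summed per library and cell class. A class was tested where every library held at least 10 nuclei of it, which left 15 classes. edgeR 4.0.16 (R 4.3.3) filtered genes with filterByExpr, scaled with TMM and fitted a quasi-likelihood model with age, sex and genotype. The genotype effect within each age and its difference between ages came from a model of the 4 group means with sex. The difference of the genotype effect between sexes came from a model with that interaction. P-values were adjusted by Benjamini-Hochberg within class and contrast, and a gene was called at an adjusted p under 0.05. All tests were two-sided. Log2 fold changes are cre over control or P192 over P31, and SE is the standard error of the fitted value. Means of counts per 1000000 (CPM) are given with their SD across libraries. Numbers of nuclei per class were tested with the same edgeR model, with the library's nuclei as the total. Ratios of classes along a lineage were compared in the 4 pairs of the same age and sex by an exact sign-flip permutation test, whose smallest p is 0.125.

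The 27 gene lists, of 517 genes, were tested with limma's camera (3.58.1) at a preset inter-gene correlation of 0.01, where at least 5 members were measured, with adjustment over lists within class and contrast. They covered BACE1 substrates, secretase and APP processing genes, the Notch pathway, and neuregulin and ErbB signalling. Oligodendrocyte lists covered precursor genes, newly formed oligodendrocyte genes, mature myelin genes and cholesterol biosynthesis. Neuronal lists covered immature and mature granule neuron genes, immediate early genes, ionotropic glutamate receptors, metabotropic glutamate receptors with the postsynaptic scaffold, GABA receptors and transporters, presynaptic release genes, voltage-gated sodium and potassium channels, and axon guidance genes. The remaining lists covered cytosolic ribosomal proteins, nuclear-encoded respiratory chain genes, mitochondrially encoded genes, heat shock and unfolded protein genes, disease-associated and homeostatic microglia genes, reactive and homeostatic astrocyte genes, interferon response genes and cell cycle genes. The same test with an estimated correlation, and fry, stand beside camera. Fry tests whether the genes of a list move one way on balance, without comparing them with other genes.

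Named genes follow a rule. For genotype, in each tested class, these were the 4 higher and 4 lower genes of smallest p among those called and moved the same way in all 4 pairs, with Bace1, Thy1 and called list members. For age, the rule took the 4 higher and 4 lower genes of smallest p that moved the same way in all 4 pairs of the same genotype and sex, in the granule neuron, oligodendrocyte, precursor, astrocyte and microglia classes, up to 30 genes, filled in order of p. For the effects at each age and the interactions it took the 3 of smallest adjusted p in each class, up to 12 genes. Where no gene passed, the 3 of smallest p are given as values, and list members used as examples are those of smallest p. Genes known only by a clone or model number, sex-linked genes of known role and mitochondrially encoded genes counted but were not named by the rule. Genes named outside it were chosen after their values were seen and are said to be.

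The procedure was tested on simulated counts, drawn for each gene on its own from means and spreads fitted to the real libraries. In them 200 genes were changed 1.5-fold or 2-fold between groups, and the cholesterol biosynthesis list 1.5-fold. Such counts hold no correlation between genes, so the rates may not carry over to the real libraries. In neuroblast-like counts (9600 genes), edgeR recovered 27.0% of genes changed 1.5-fold and 67.0% of genes changed 2-fold, with 7.69% of its calls false. DESeq2 1.42.0 recovered 10.7% and 43.8% there. In DG granule neuron-like counts, edgeR recovered 70.0% and 87.0%, and in mature oligodendrocyte-like counts 41.0% and 81.0%, with 3.37% and 2.88% of calls false. The false share was 8.16% in precursor-like and 7.79% in microglia-like counts, and 9.15% for age in mature oligodendrocyte-like counts. A list planted in neuroblast-like counts gave an adjusted p of 4.72e-09 with the preset correlation and 0.822 with the estimated one. With the estimated one it gave 0.24 in microglia-like, 0.00979 in mature oligodendrocyte-like, 0.0303 in DG granule neuron-like and 0.0223 in precursor-like counts, and 0.00362 for age in mature oligodendrocyte-like counts.

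Alternatives were DESeq2 size factors, the DESeq2 Wald test, no low-count filter, no sex term, the 4 pairs as a replicate block, doublets kept, all deposited barcodes, clustering resolutions of 0.5 and 2, thinning to the smallest total, and leaving out each library. Where a library was left out of an arm of 2, the lone library was assumed to vary like the others. Added after seeing the data were a fit without the 2 pairs whose control library held many low-UMI nuclei, a minimum of 5 nuclei per library, totals of nuclei without the low-UMI cluster, shares tested at each age, neuronal classes summed for Bace1 and Thy1, neuroblast-like nuclei without those with an interneuron precursor UMI, and mature oligodendrocyte-like nuclei of cluster_1 alone and of cluster_8 alone. Python 3.11.15 and matplotlib 3.10.9 were used. Raw reads and protein levels were not used here. Single gene results for a few genes are not reported here.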

Results

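Nuclei of the hippocampus were sequenced from 8 mice, 4 control mice with floxed Bace1 alleles and 4 cre mice with the same alleles and Thy1-cre, at P31 and at P192. After filtering, the P31 control libraries held 8865 (female) and 8872 (male) nuclei, and the P31 cre libraries 6744 (female) and 8558 (male). At P192 the control libraries held 8690 (female) and 8944 (male) nuclei, and the cre libraries 7215 (female) and 7640 (male). The analysed UMIs, in units of 1000000, came to 41.2 and 51.7 in the P31 control libraries and 39.4 and 42.6 in the P31 cre libraries, female first. They came to 46.9 and 41.8 in the P192 control libraries and 43.5 and 38.4 in the P192 cre libraries. The median nucleus held 2454.5 to 4178 UMIs and 1345 to 1987 genes. Xist, the transcript of the inactive X chromosome, was at 1540 to 1774 CPM in the libraries labelled female and at most 2.47 CPM in those labelled male. The 65528 nuclei included 8471 in clusters left unnamed. One of these clusters held nuclei with few UMIs and took 17.4% of the P192 male control and 19.1% of the P31 female control library, against 1.42% to 5.36% of the other 6. Ttr (ENSMUSG00000061808, chr18:20665280-20674321), the thyroxine carrier made by choroid plexus, was at 683 CPM in the P192 male cre library, 35.5 CPM in the P192 female cre library and at most 6.00 CPM elsewhere. Choroid plexus-like nuclei made up 1.66% of the P192 male cre library against 0.425% of its control. In the P192 females they made up 0.347% in the cre library and 0.127% in the control.

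Bace1 (ENSMUSG00000032086, chr9:45838580-45864399, plus strand) encodes the beta-secretase that cleaves APP, and Thy1-cre was bred in to delete it in neurons. Over the summed neuronal classes, Bace1 stood at 30.1 CPM in the P31 female control and 22.0 in its cre counterpart, and at 28.8 against 22.7 CPM in the P31 males. At P192 it stood at 21.9 against 22.1 CPM in the females and 27.8 against 21.2 CPM in the males. The means were 27.1 ± 3.59 CPM in control and 22.0 ± 0.617 CPM in cre libraries (SD, n = 4 each), a log2 fold change of -0.30 (SE 0.08), or 18.5% less. It was lower in 3 of 4 pairs of the same age and sex (exact sign-flip p = 0.25, the smallest p possible with 4 pairs being above 0.05), and in edgeR its unadjusted p was 0.0034 and its adjusted p over all genes 0.996. At P31 the log2 fold change was -0.40 and at P192 -0.19. By class, the log2 fold change was -0.40 in subiculum or cortical neurons, -0.35 in CA3, -0.26 in CA1, DG granule and inhibitory neurons, and -0.04 in mature oligodendrocyte-like nuclei. Mature oligodendrocyte-like nuclei held the most Bace1 of these, 85.4 ± 25.8 CPM in control and 84.5 ± 26.3 CPM in cre (SD, n = 4 each). Thy1 (ENSMUSG00000032011, chr9:44043384-44048579), a neuronal surface glycoprotein whose promoter drives the transgene, stood at 149 ± 29.3 against 158 ± 10.7 CPM (log2 fold change 0.09, SE 0.08). The labels do not say which exon is floxed, so counts at the end of the transcript need not fall when the gene is deleted.

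**Figure D1:**
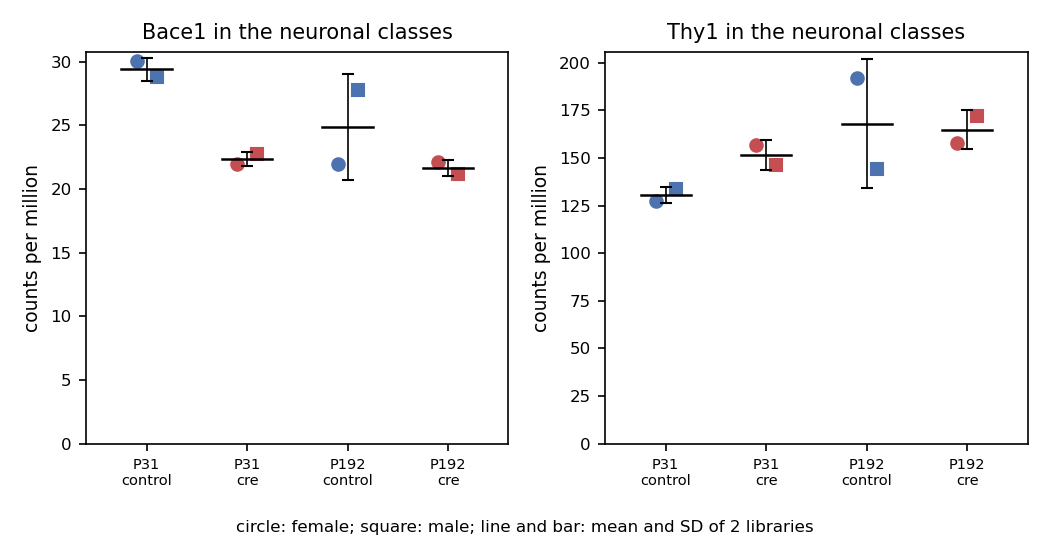
CPM of Bace1 and Thy1 over the summed neuronal classes in each of the 8 libraries, by age and genotype (circles female, squares male, line and bar mean and SD of 2 libraries). Bace1 lay between 21.2 and 22.7 CPM in the 4 cre libraries and between 21.9 and 30.1 CPM in the 4 control libraries.

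The comparison of cre with control mice asks what loss of neuronal BACE1 does to each cell class, and the title names neuroblasts and oligodendrocytes. In neuroblast or immature granule neuron-like nuclei, 4 genes fell in cre mice. Nrxn3 (ENSMUSG00000066392, chr12:88722876-90334935), a presynaptic adhesion molecule, fell from 1410 ± 987 to 400 ± 253 CPM (SD, n = 4 each; log2 fold change -1.73, SE 0.24, adjusted p = 6.6e-05). Il1rapl2 (ENSMUSG00000059203, chrX:137570608-138846946), of the interleukin 1 receptor family, fell by 1.22 log2 (SE 0.20, adjusted p = 0.00135) and was lower in 4 of 4 pairs. Dlx6os1 (ENSMUSG00000090063, chr6:6820189-6871592), a long noncoding RNA antisense to Dlx6, a homeobox gene of interneurons, decreased by 1.93 log2 (SE 0.32, adjusted p = 0.00135). Meis2 (ENSMUSG00000027210, chr2:115863064-116065839), a homeobox gene, dropped by 0.96 log2 (SE 0.20, adjusted p = 0.039). Nrxn3 and Meis2 were lower in 3 of 4 pairs and Dlx6os1 in 3 with 1 pair at 0 in both, so these 3 were named after their values were seen. Of them, Nrxn3 stayed called without any single library, while the P31 libraries decided the rest. The adjusted p of Il1rapl2 was 0.796 without P31 control replicate 2 and 0.618 without P31 cre replicate 2. For Dlx6os1 it was 1.00 without P31 control replicate 1 and 0.0808 without P31 cre replicate 2, and its log2 fold change was -3.26 without P31 control replicate 2. For Meis2 it was 0.439, 0.0562 and 0.263 without P31 control replicate 1, P31 cre replicate 1 and P31 cre replicate 2. Without the 2 pairs whose control library was rich in low-UMI nuclei, Il1rapl2 was at -1.62, Nrxn3 at -0.57, Dlx6os1 at -1.32 and Meis2 at -0.71 log2. That fit held 1 library of each age and genotype, so its adjusted p-values, small or large, carry little weight. Meis2 also passed no longer with no sex term (adjusted p = 0.133). The DESeq2 Wald test called none of the 4. Few nuclei of the class held Dlx6os1, 2.73% in P31 control and 1.28% in P31 cre mice, and 1.79% and 1.14% at P192.

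**Figure D2:**
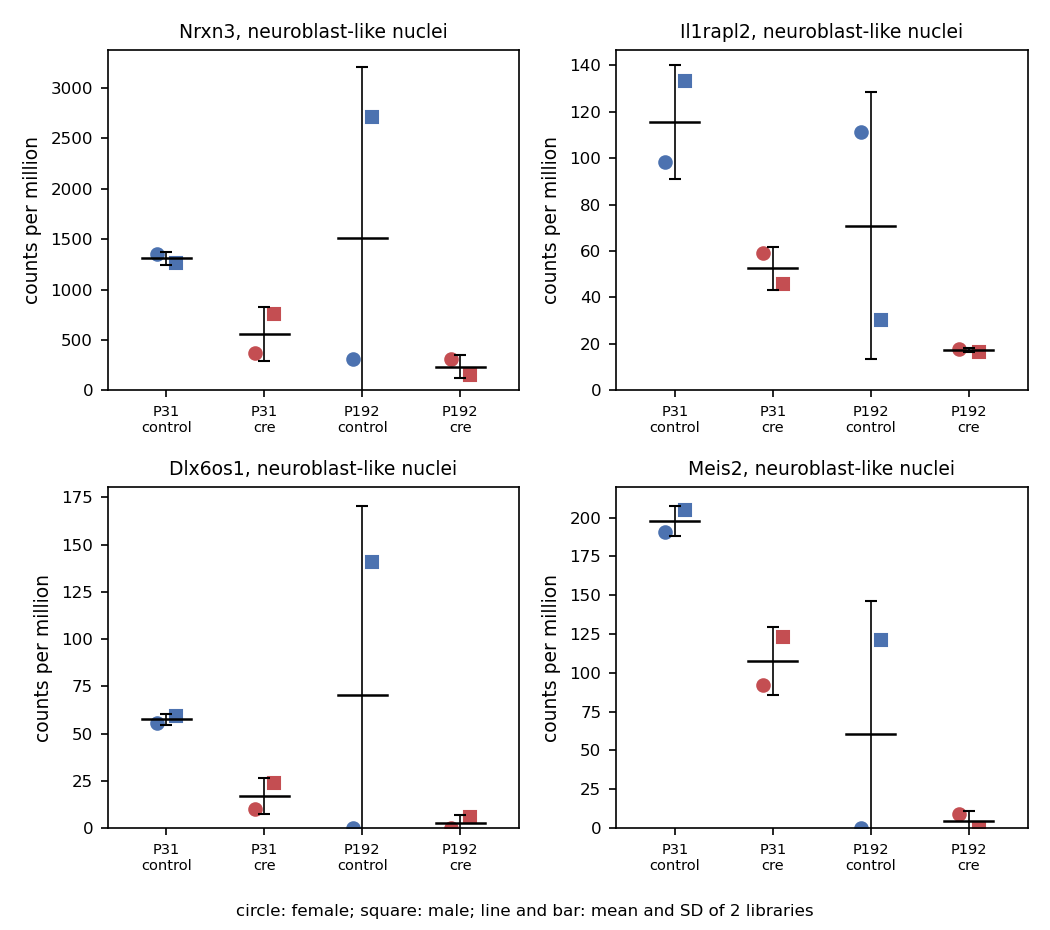
CPM of Nrxn3, Il1rapl2, Dlx6os1 and Meis2 in neuroblast or immature granule neuron-like nuclei of each of the 8 libraries, by age and genotype (circles female, squares male, line and bar mean and SD of 2 libraries, with bars that would pass below 0 ending at the axis). Il1rapl2 lay between 30.2 and 133 CPM in control and between 16.7 and 59.2 CPM in cre libraries.

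In oligodendrocyte precursor-like nuclei, Scel (ENSMUSG00000022123, chr14:103513342-103612797), which encodes sciellin, rose from 63.1 ± 17.2 to 114 ± 47.8 CPM (SD, n = 4 each; log2 fold change 0.82, SE 0.15, adjusted p = 0.0159). Col19a1 (ENSMUSG00000026141, chr1:24261890-24587472), a collagen gene, rose by 1.21 log2 (SE 0.23, adjusted p = 0.0281), and Ttr by 2.63 log2 (adjusted p = 0.00138). All 3 were higher in 4 of 4 pairs, and Ttr was at 0.66 log2 (adjusted p = 0.991) without P192 cre replicate 1 and 1.95 (adjusted p = 0.533) without P192 control replicate 1. Scel passed no longer without P192 cre replicate 1 (adjusted p = 0.327), P192 control replicate 2 (0.11), P192 cre replicate 2 (0.141) or P31 cre replicate 1 (0.0645). Col19a1 passed no longer without any one P31 library or P192 cre replicate 1, with adjusted p between 0.102 and 0.701. It is also among the leading genes of an inhibitory neuron-like cluster, and whether RNA of those neurons entered these counts was not tested. Without the 2 pairs named above, Scel and Col19a1 passed no longer (adjusted p = 0.0905 and 0.146), and Ttr was not tested. The DESeq2 Wald test called none of these 3, and Ttr passed no longer with no sex term (adjusted p = 0.0805). Tafa1, which encodes a secreted chemokine-like protein, fell in perivascular macrophage-like nuclei from 995 ± 596 to 100 ± 95.3 CPM (log2 fold change -3.27, SE 0.41, adjusted p = 0.03). Tafa1 is also among the leading genes of the low-UMI cluster and of CA1 and CA3 clusters. Its adjusted p was 0.112 without P192 control replicate 1, 0.127 without P31 cre replicate 2, 0.0922 with no sex term, 0.0689 with doublets kept and 0.0809 with all deposited barcodes. The DESeq2 Wald test called Tafa1 and 47 genes in all in this class, 42 of them lower, and 40 at P31. Inhibitory neuron-like nuclei gave the remaining 2 calls, named after their values were seen. There Ttr rose by 3.89 log2 (adjusted p = 0.029, but 1.22 log2 without P192 cre replicate 1, 2.27 without P192 control replicate 1, and lost too without either replicate 2 control library), as did Gm34544, an unnamed transcript (2.16, adjusted p = 0.0167, and 0.0534 to 0.169 without 1 of 4 libraries). Gm34544 is also among the leading genes of the mossy cell-like cluster. That class made up 0.248% of nuclei in P31 control and 0.61% in P31 cre mice, and 0.267% and 0.214% at P192. Gm34544 was at 0.97 log2 (adjusted p = 0.924) with doublets kept and 0.96 (adjusted p = 0.977) with all deposited barcodes. Both calls were lost with no sex term (adjusted p = 0.916), and that of Ttr also with doublets kept, with all deposited barcodes and in the DESeq2 Wald test (2.21 log2).

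No gene was called by genotype in the other 11 of 15 classes with edgeR. At an unadjusted p under 0.05 these had 839 genes in astrocytes, 770 in mature oligodendrocytes, 664 in DG granule neurons, 552 in microglia, 485 in CA3, 472 in CA1 and 390 in subiculum or cortical neurons. The others had 226 in mossy cells, 205 in fibroblasts, 175 in Cajal-Retzius cells and 73 in endothelial cells. The DESeq2 Wald test called 3 genes in DG granule neurons, 1 in fibroblasts and 0 in the other 9. Genes of smallest p in mature oligodendrocyte-like nuclei were Pde1a at -0.98, Errfi1 at 0.57 and Khdrbs2 at -0.77 log2 (adjusted p = 0.202). In DG granule neuron-like nuclei they were Ccdc127 at 0.59, Il1rapl2 at 0.35 and Ttr at 3.47 log2 (adjusted p = 0.296). In astrocyte-like nuclei they were Cpne4 at -1.91, Sntg1 at -1.18 and Cntnap2 at -0.92 log2 (adjusted p = 0.131 to 0.178). In CA1 they were Nr4a3 at -0.53, Adam33 at 1.25 and Aspa at -1.05 log2, and in CA3 Tspan18 at 0.39, Ptprm at -1.12 and Abra at 0.53. In mossy cell-like nuclei they were Dpp10 at -1.35, Ntng1 at 1.12 and Gsdme at 0.86 log2, and in microglia-like nuclei Ttr at 4.18 and Ctnnd2 at -1.06. Subiculum or cortical neurons had St18 at -1.04, Ttr at 4.61 and Kcnt2 at 0.48 log2, and Cajal-Retzius cells Chrm3 at 1.92, Pard3bos1 at -1.09 and Sgcd at 1.62. Endothelial cells had Bmx at -3.07, Prdm16 at -2.17 and Sgcz at 1.84 log2, and fibroblasts Vip at -4.16, Cavin2 at 1.47 and Tll1 at 1.44. Newly formed oligodendrocyte-like nuclei, tested with a minimum of 5 nuclei, gave 0 calls in edgeR and 107 of 4586 genes at an unadjusted p under 0.05.

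Gene lists tied to BACE1 and to oligodendrocyte maturation showed no called member over all genes in any class by genotype. BACE1 substrates, the proteins the protease sheds, were called lower in 1 of 15 classes, microglia-like nuclei (median -0.34, adjusted p = 0.00011, but 0.461 with an estimated correlation). In the same nuclei neuronal and synaptic genes had a median of -0.32 log2, with a mean of -0.65 in the 2 pairs whose control library was rich in low-UMI nuclei and 0.09 in the other 2. Secretase and APP processing genes and the Notch pathway were called in 0 classes (smallest adjusted p = 0.0556 and 0.0861). Over the list alone, 2 Notch members were higher, both in astrocyte-like nuclei, the Notch modifier Lfng at 0.57 and the Notch target Hes1 at 0.49 log2. Neuregulin and ErbB signalling was lower in 1 of 11 classes, neuroblast-like nuclei (median -0.15, adjusted p = 0.186 with an estimated correlation). Newly formed oligodendrocyte genes were called in 0 of 14 classes (smallest adjusted p = 0.0638), and their smallest p in mature oligodendrocyte-like nuclei belonged to Sema5a at 0.34 and Frmd4a at -0.29 log2. Precursor genes were lower in 4 of 14 classes, in none of them with an estimated correlation (smallest adjusted p = 0.186). Mature myelin genes were higher in mature oligodendrocyte-like nuclei (median 0.12, adjusted p = 0.44 with an estimated correlation), where Hapln2 stood at 0.26, Gjb1 at 0.33 and Ptgds at 0.27 log2. They were lower in 8 of 13 classes, among them subiculum or cortical neurons (-0.57, adjusted p = 0.108 with an estimated correlation), astrocytes (-0.42) and DG granule neurons (-0.26). Cholesterol biosynthesis was higher in 3 of 12 classes, with a median of 0.11 in mature oligodendrocyte-like nuclei (adjusted p = 0.00863, but 0.541 with an estimated correlation). In neuroblast-like nuclei immature granule neuron genes were higher (median 0.12, adjusted p = 0.0368, but 0.502 with an estimated correlation), with Dcx at 0.32, Igfbpl1 at 0.23 and Dpysl3 at 0.26 log2. They were lower in mature oligodendrocyte-like nuclei (median -0.06, adjusted p = 0.0121, but 0.44 with an estimated correlation). Mature granule neuron genes were lower there (median -0.29, adjusted p = 0.186 with an estimated correlation) and in 7 of 15 classes in all.

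Of 357 tests of lists by genotype, 93 were called with the preset correlation, 0 with the estimated one (smallest adjusted p = 0.108) and 1 with fry. The counts that follow thus hold for the preset correlation only. In simulated counts camera with the estimated correlation missed a planted list in neuroblast-like (adjusted p = 0.822) and microglia-like nuclei (0.24). In these classes a miss with it therefore cannot decide whether a list moved. Metabotropic glutamate receptors with the postsynaptic scaffold were lower in 8 of 15 classes, ionotropic glutamate receptors in 6, presynaptic release genes in 6, axon guidance genes in 5, sodium and potassium channels in 4 and GABA genes in 2 of 14. Mitochondrially encoded genes were lower in 8 classes and higher in 1, ribosomal proteins lower in 5 and higher in 1, respiratory chain genes lower in 3, and immediate early genes lower in 1. Heat shock and unfolded protein genes were called in 0 of 15 (smallest adjusted p = 0.0556). Disease-associated microglia genes were higher in 3 classes, homeostatic microglia genes in 2, interferon genes in 3, cell cycle genes in 2 and reactive astrocyte genes in 1, and homeostatic astrocyte genes were higher in 1 and lower in 4. Over the list alone, 36 tests of mitochondrially encoded members, 23 of postsynaptic scaffold members and 19 of myelin members were lower. The 2 libraries rich in low-UMI nuclei were both controls.

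At P31, 9 genes were called across 15 classes, with 66 of 357 list tests called at the preset correlation and 0 with the estimated one. In neuroblast-like nuclei Il1rapl2 fell by 1.17 log2 (adjusted p = 0.0102), Dlx6os1 by 1.73 (adjusted p = 0.0159) and Nrxn3 by 1.34 (adjusted p = 0.0204), with Meis2 also lower and Gm47283 higher. Gm47283 is annotated on chromosome Y (chrY:90784738-90816464), and each genotype held 1 male at P31. In perivascular macrophage-like nuclei Hs6st3 (-4.94 log2, adjusted p = 0.0241), Cntnap2 (-3.47), Ntm (-3.84) and Magi2 (-3.08) fell. This class held only 30 to 34 nuclei in each P31 library, and 19.1% of the nuclei of P31 control replicate 1 lay in the low-UMI cluster. Whether free RNA of other cells entered these counts was not tested. Each of the 9 was lost on leaving out at least 1 P31 library. Nrxn3 was at -0.62 log2 (adjusted p = 1.00) without P31 control replicate 1. Il1rapl2 was at -0.64 (adjusted p = 1.00) without P31 control replicate 2, with adjusted p = 0.33 and 1.00 without P31 cre replicates 1 and 2. Hs6st3, Cntnap2, Ntm and Magi2 passed no longer without either P31 cre library (adjusted p = 0.262 to 0.481), Gm47283 without those or P31 control replicate 2 (0.322 to 1.00), and Dlx6os1 and Meis2 without any one P31 library (0.203 to 1.00).

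At P192, 35 genes were called, 27 of them in DG granule neuron-like nuclei, with 81 of 357 list tests called at the preset correlation and 0 with the estimated one. There Ddn (ENSMUSG00000059213, chr15:98803777-98809490), which encodes the postsynaptic protein dendrin, fell by 0.77 log2 (adjusted p = 0.00364), and Hsp90ab1, a heat shock chaperone, fell by 0.63 (adjusted p = 0.0128). Ttr rose by 4.54 log2 (adjusted p = 0.000385) in the same nuclei. Mitochondrially encoded genes fell in 11 of 12 list members over all genes and 12 adjusted over the list alone (median -0.87, adjusted p = 0.0766 with an estimated correlation). Ribosomal proteins fell in 1 of 27 over all genes and 22 adjusted over the list alone (median -0.44, adjusted p = 0.292 with an estimated correlation). The median mitochondrial share of all nuclei was 0.215% in the P192 female cre library, 0.456% in its control, 0.385% in the male cre library and 0.44% in its control. Ttr also rose in inhibitory neurons, mature oligodendrocytes, precursors and subiculum or cortical neurons, by 3.05 to 6.35 log2. The choroid plexus-like share was higher in both P192 cre libraries too, so a change of Ttr within these classes is not shown. In CA3, Ptgds, prostaglandin D2 synthase, rose by 1.05 log2 (SE 0.16, adjusted p = 0.0413) and mt-Nd2 fell by 1.15 log2. Ptgds also leads a fibroblast or leptomeningeal cluster, and that class made up 4.03% of the P192 male cre library against 0.794% of its control, and 1.29% against 2.13% in the females. In neuroblast-like nuclei Nrxn3 fell by 2.68 log2 (SE 0.41, adjusted p = 0.000429), but by 0.61 (adjusted p = 0.876) without P192 control replicate 1. In precursor-like nuclei Scel rose by 1.08 log2 (adjusted p = 0.0177). In DG granule neurons Ttr was at 2.07 log2 (adjusted p = 0.213) without P192 cre replicate 1 and 3.74 (adjusted p = 0.489) without P192 control replicate 1, and it was lost without either library in the other 4 classes too. Ptgds in CA3 was lost without any one P192 library (adjusted p = 0.0788 to 0.403), and Ddn without P192 control replicate 1 or either P192 cre library (0.0563 to 0.0763). Hsp90ab1 was lost without P192 control replicate 1 or P192 cre replicate 2 (0.274 and 0.376), and mt-Nd2 in CA3 without either P192 control or P192 cre replicate 2 (0.079 to 0.345). Scel was lost without P192 control replicate 2 or any one cre library (0.1 to 0.651).

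The genotype effect differed between ages for 10 genes and between sexes for 5 tests of a single gene. Ddn in DG granule neurons differed by -1.02 log2 between P192 and P31 (adjusted p = 0.0228, but 0.0571 to 0.108 without 1 of 7 libraries, all but P31 control replicate 1) and Ptgds in CA3 by 2.05 (adjusted p = 0.01), the latter at 1.85 (adjusted p = 0.0819) without P31 control replicate 1. In neuroblast-like nuclei the kinase gene Mapk8 differed by 2.74 log2 (adjusted p = 0.0364, but 0.311 without P192 control replicate 2). The effect on Nrxn3 was not called different between the ages. By sex, the calls were all of Gm12160 (ENSMUSG00000087089, chr11:45160943-45213656), a long intergenic RNA. In mature oligodendrocyte-like nuclei it had 0 UMIs in the P192 male control, 210, 255 and 246 in the other P192 libraries and 0 in every P31 library.

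Among cell classes, neuroblast-like nuclei made up 4.95% ± 1.16 of nuclei in P31 control and 6.61% ± 0.296 in P31 cre mice, and 0.317% ± 0.058 against 0.591% ± 0.052 at P192 (SD, n = 2 each). Newly formed oligodendrocyte-like nuclei made up 1.39% ± 0.095 against 1.17% ± 0.266 at P31 and 0.244% ± 0.045 against 0.206% ± 0.18 at P192. Mature oligodendrocyte-like nuclei made up 10.1% ± 1.93 against 7.53% ± 1.23 at P31 and 21.8% ± 0.331 against 23.5% ± 1.53 at P192. No class of 18 was called by genotype in edgeR, and 1 had an unadjusted p under 0.05. That class was neuroblast-like nuclei, higher in 4 of 4 pairs by 0.65 log2 (SE 0.16, adjusted p = 0.149). DESeq2 was not run on shares. Without the low-UMI nuclei in the total, the difference was 0.52 log2 (adjusted p = 0.495). The genotype difference in the mature share was -0.42 log2 at P31 and 0.10 at P192, and the difference between the ages was 0.52 log2 (unadjusted p = 0.12). With the low-UMI nuclei out of the total, the mature share differed by -0.55 log2 at P31 (edgeR unadjusted p = 0.0417, adjusted p = 0.563) and -0.00032 at P192. Over the 4 pairs, the log2 ratio of neuroblast-like to DG granule neuron-like nuclei was higher in cre mice by 0.33 (SD 0.488, exact sign-flip p = 0.375). The ratio of newly formed to mature oligodendrocyte-like nuclei differed by -0.27 (SD 0.918, exact p = 0.875, and -0.47 to 0.18 with 1 library left out, the P192 male cre library holding 6 newly formed nuclei) and that of precursor to mature by 0.38 (SD 0.447, exact p = 0.25), all within the spread between pairs.

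**Figure D3:**
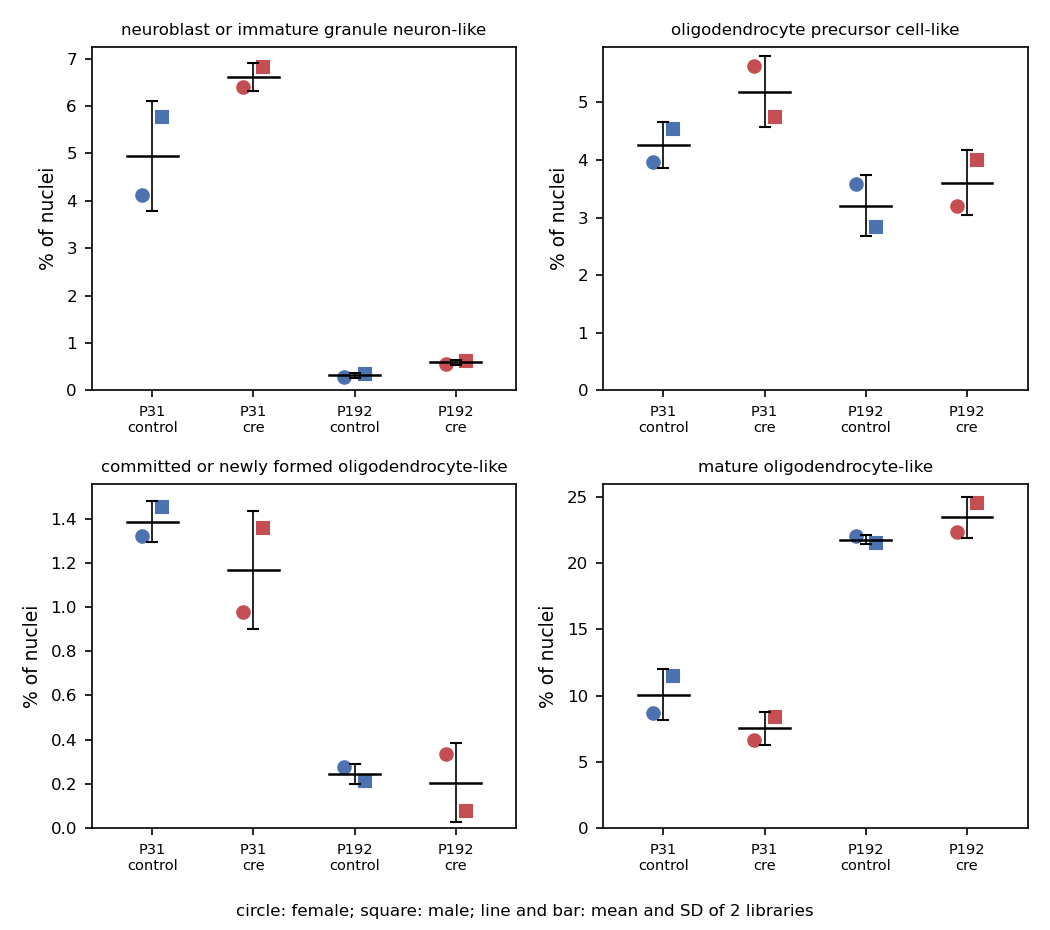
Share of all nuclei (%) that were neuroblast or immature granule neuron-like, precursor-like, newly formed and mature oligodendrocyte-like in each of the 8 libraries, by age and genotype (circles female, squares male, line and bar mean and SD of 2 libraries). Neuroblast-like nuclei averaged 5.78% at P31 and 0.454% at P192, and mature oligodendrocyte-like nuclei 8.80% and 22.6%.

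The comparison of ages asks how the cell classes differed between young and adult mice, in both genotypes. Age and library order coincide, so no age effect here can be told apart from a day or batch effect. The neuroblast-like share fell from 5.78% ± 1.18 at P31 to 0.454% ± 0.165 at P192 (SD, n = 4 each; log2 fold change -3.71, SE 0.18, adjusted p = 3.22e-05). The newly formed oligodendrocyte-like share fell by 2.56 log2 (SE 0.41, adjusted p = 0.00695) and the mature share rose from 8.80% ± 1.98 to 22.6% ± 1.33 (log2 fold change 1.39, SE 0.17, adjusted p = 0.00261). The astrocyte-like share fell from 10.6% to 5.42% (log2 fold change -0.96, SE 0.19, adjusted p = 0.0124), but was at -0.98 (adjusted p = 0.0541) without P192 control replicate 2. Precursor-like nuclei were lower in 4 of 4 pairs, by 0.47 log2 (adjusted p = 0.0882). Shares of a library add up to its total, so the rise of the mature share by itself lowers the others. A lower share thus need not mean fewer cells of a class. The p-values measure spread between these libraries, each from 1 animal.

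In mature oligodendrocyte-like nuclei 1761 genes rose and 1904 fell with age, but different clusters held most of the class at each age. These were cluster_8 with 2699 nuclei at P31 and 217 at P192, cluster_1 with 209 and 6132, and cluster_19 with 47 and 982. Within cluster_1 alone 270 genes were called with age and within cluster_8 alone 107, in fits added after the data were seen. The P31 libraries held 14 to 125 nuclei of cluster_1 each, and the P192 libraries 36 to 85 of cluster_8. Fewer calls within these clusters may thus also come from few nuclei. Il33 (ENSMUSG00000024810, chr19:29925114-29960718), a nuclear cytokine, rose from 27.3 ± 9.12 to 533 ± 58.2 CPM (SD, n = 4 each; log2 fold change 4.26, SE 0.15, adjusted p = 2.42e-12). Abca8a, a lipid transporter, rose from 21.1 to 410 CPM (4.24 log2), the F-box gene Fbxw15 rose by 3.13 log2, and Neat1, the scaffold RNA of paraspeckles, rose by 2.64. Man1a, a Golgi mannosidase, fell from 819 to 123 CPM (-2.72 log2), Kank1, a regulator of the cytoskeleton, from 143 to 13.1 CPM (-3.43), and the claudin Cldn14 and the protease Masp1 by 2.85 and 3.47 log2. Within cluster_1 and cluster_8, Il33 rose by 3.22 and 2.61 log2, Abca8a by 3.17 and 2.02 and Neat1 by 1.32 and 1.37, and Masp1 fell by 3.52 and 2.17, all called. Fbxw15, Man1a, Kank1 and Cldn14 were called within cluster_1 and not within cluster_8, where Man1a was at 0.12 and Kank1 at 0.25 log2. Cholesterol biosynthesis fell in 19 of 22 measured genes over all genes and 20 adjusted over the list alone, with 0 higher (median -1.27, adjusted p = 0.36 with an estimated correlation, fry adjusted p = 0.00506). Hmgcs1 (ENSMUSG00000093930, chr13:119690379-119708260), the synthase that makes HMG-CoA, fell by 2.25 log2, the lanosterol demethylase Cyp51 by 1.77 and Msmo1 by 1.56. Within cluster_1 the list had 2 of 19 called lower (median -0.52) and within cluster_8 3 of 20 (median -0.83), with Hmgcs1 and Cyp51 called in both. Insig1, Dhcr7 and Tm7sf2 did not pass. Newly formed oligodendrocyte genes fell in 12 of 18 and rose in 2 (median -0.53, adjusted p = 0.386 with an estimated correlation), with Gpr17 at -2.67, 9630013A20Rik at -3.05, and Tmem163 at -1.80 log2, while Mpzl1 rose. Mature myelin genes went both ways, 8 of 23 up and 11 down (median -0.13, mean 0.13, adjusted p = 0.80). Mog, a myelin surface protein, fell by 0.95 log2, whereas Apod rose by 0.94 and Hapln2 by 0.82. BACE1 substrates rose in 11 of 20 and fell in 4 (median 0.51, adjusted p = 0.386 with an estimated correlation), with Sez6l2 at 1.03, App at 0.70, Aplp1 at 0.71 and Chl1 at 0.97 log2. Ribosomal proteins rose in 21 of 27 (median 0.60, adjusted p = 0.421 with an estimated correlation) and interferon genes in 5 of 9 with 1 lower (adjusted p = 0.386 with an estimated correlation), among them Xaf1, H2-D1 and Ifi27, the last by 1.24 log2.

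In DG granule neuron-like nuclei 1874 genes were called with age. The class lay in cluster_0, with 5086 nuclei at P31 and 3366 at P192, and cluster_3, with 1430 and 3019. Camk2d (ENSMUSG00000053819, chr3:126596302-126846326), a calcium and calmodulin dependent kinase, rose from 7.01 ± 1.22 to 30.1 ± 3.63 CPM (SD, n = 4 each; log2 fold change 2.12, SE 0.11, adjusted p = 2.46e-09). Rasgrp1, an activator of Ras, rose by 1.15 log2, and Zfp804b and the cadherin Cdh18 by 1.04 and 1.01. Robo1, a receptor for the guidance cue Slit, fell from 403 ± 33.5 to 157 ± 7.94 CPM (log2 fold change -1.36, SE 0.06, adjusted p = 2.32e-10), Pcdh15 fell by 1.74 log2 and Il1rapl2 by 1.06. Igfbpl1, a gene of newborn neurons, fell by 4.31 log2, beside a fall of 5.55 log2 in astrocyte-like nuclei and of 3.71 log2 in the neuroblast-like share. Immature granule neuron genes fell in 4 of 14 over all genes and 5 adjusted over the list alone (median -0.12, adjusted p = 0.523 with an estimated correlation), among them Dcx at -1.08, Dpysl3 at -1.01 and Plxna4 at -0.17. Mature granule neuron genes went both ways, 6 of 19 up and 6 down (median -0.03, mean 0.03, adjusted p = 0.867), with Ntng1 at 0.91, Plk5 at 1.15 and Tdo2 at -1.10 log2. Immediate early genes rose in 5 of 18, Egr3 by 0.87 and Npas4 by 1.86, and heat shock and unfolded protein genes in 9 of 19, Xbp1 by 0.50 and Ddit3 by 1.14, with 0 lower in either list (adjusted p = 0.523 for each with an estimated correlation). Axon guidance genes fell in 9 of 27 and rose in 3 (median -0.11, adjusted p = 0.523 with an estimated correlation). Without the 2 pairs with a control library rich in low-UMI nuclei, 797 genes were called. That fit compared 2 P192 female with 2 P31 male libraries, so its age calls cannot be told apart from sex. The DESeq2 Wald test called 1167.

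In oligodendrocyte precursor-like nuclei 207 genes were called with age. Ralyl, an RNA-binding protein gene, rose by 0.92 log2 (SE 0.08, adjusted p = 4.71e-10), the connexin Gjc3 by 0.96, Cdh19 by 1.26 and Ebf1 by 1.61. Col19a1 fell from 46.9 ± 21.2 to 6.70 ± 3.76 CPM (SD, n = 4 each; adjusted p = 3.96e-09), and Ano3, Kcnmb2 and Schip1 fell by 1.17, 1.68 and 0.75 log2. Col19a1 and Kcnmb2 are also among the leading genes of an inhibitory neuron-like cluster, so a change of these 2 within precursors is not shown. Astrocyte-like nuclei gave 242 calls, with Brinp3 higher by 1.39 log2, Cdh19 by 1.37, Luzp2 by 1.01 and Cped1 by 1.66, and with the matrix gene Tnc lower by 1.75, Kcnip1 by 2.24 and Adgrv1 by 1.58. The class lay in cluster_4, with 2510 nuclei at P31 and 1434 at P192, and cluster_16, led by Tnc and Adgrv1 among others, with 945 and 342. Microglia-like nuclei gave 147 calls. There homeostatic genes fell in 4 of 13 over all genes and 9 adjusted over the list alone (median -0.47, adjusted p = 0.69 with an estimated correlation), among them Csf1r by 0.49 log2. CA1 gave 332 calls, and CA3 85 higher and 107 lower. Mossy cells gave 87 calls, inhibitory neurons 84, neuroblasts 60, Cajal-Retzius cells 20, fibroblasts 12, subiculum or cortical neurons 2 and macrophages 1. Endothelial cells gave 0 in edgeR, 298 at an unadjusted p under 0.05, and 1 with the DESeq2 Wald test.

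Across classes, the age lists divided as follows, with 103 of 357 tests called at the preset correlation, 0 with the estimated one (smallest adjusted p = 0.0773) and 21 with fry. Heat shock and unfolded protein genes were higher in 8 of 15 classes, mature myelin, ribosomal and interferon genes in 6 each and immediate early genes in 5. Ribosomal proteins were lower in 2 classes and immediate early genes in 1. Immature granule neuron genes were lower in 6 of 9 and higher in 0. Mitochondrially encoded genes were higher in 4 classes and lower in 4. Cholesterol biosynthesis was higher in 3 classes and lower in 2. Disease-associated microglia genes were higher in 4 and lower in 2, and BACE1 substrates, postsynaptic scaffold and presynaptic release genes were each higher in 3 and lower in 1. GABA genes were higher in 2 and lower in 2, axon guidance genes higher in 2 and lower in 4, and mature granule neuron genes higher in 2 and lower in 1. The Notch pathway was higher in 2, precursor genes lower in 2, newly formed oligodendrocyte genes lower in 1, channels higher in 1 and reactive astrocyte genes higher in 1. Neuregulin signalling, ionotropic receptors, respiratory chain and homeostatic microglia genes were each higher in 1 and lower in 1, and homeostatic astrocyte genes higher in 1 and lower in 3. Secretase and APP processing genes and cell cycle genes were called in 0 classes (smallest adjusted p = 0.0662 and 0.177).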

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

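Chosen only after the result was seen were the tests of free RNA of inhibitory neurons, of the low-UMI nuclei, of free RNA of all sources, of free RNA with cholesterol genes and of clusters within the mature oligodendrocytes, the precursor and young oligodendrocyte gene sets, the neuroblast gene set and the fit without 2 pairs.

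Ptgds in CA3 pyramidal neuron-like nuclei differed in its genotype effect between P192 and P31 by 2.05 log2 (SE 0.26, adjusted p = 0.01). In DG granule neuron-like nuclei the genotype effect differed between the ages for 6 mitochondrially encoded genes. These differences were -0.95 log2 for mt-Nd4, -0.88 for mt-Nd1, -0.87 for mt-Cytb, -0.97 for mt-Atp6, -0.91 for mt-Co2 and -0.92 for mt-Nd2 (adjusted p = 0.0101 to 0.0228). Of these, each passed no longer without P192 control replicate 2 (adjusted p = 0.108 to 0.138). The postsynaptic gene Ddn differed there by -1.02 log2 (SE 0.16, adjusted p = 0.0228). In neuroblast-like nuclei Ttr differed between the ages by 5.36 log2 (SE 1.02, adjusted p = 0.0364) and Mapk8 by 2.74 log2 (SE 0.54, adjusted p = 0.0364). Ttr there rested on 38 UMIs in the P192 male cre library, 31 in the P31 male control library and 0 to 5 in the other 6.

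The genotype effect on Gm12160 differed between males and females by 6.79 log2 in CA1, 7.90 in CA3, 8.32 in inhibitory neurons, 9.39 in mature oligodendrocytes and 7.19 in oligodendrocyte precursors (adjusted p = 0.00114 to 0.0403). These fitted values depend on the prior count, since the P192 male control library held 0 or 1 UMI of it in each class and every P31 library 0 or 1. The other P192 libraries held 41 to 255. Without P192 control replicate 1 the difference was -0.43 log2 in CA3 and in mature oligodendrocytes and -0.23 in precursors.

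Nrxn3, Il1rapl2, Dlx6os1 and Meis2 fell together in neuroblast-like nuclei of cre mice, by a mean of 1.46 log2. Refitted without the nuclei holding a UMI of 1 of 9 interneuron precursor genes, the mean was -0.87, or 0.595 of its size, between the bounds set for and against fewer interneuron-type nuclei, with Nrxn3, Il1rapl2 and Meis2 still called (adjusted p = 0.000305, 0.0241 and 0.0241) and Dlx6os1 left with 8 and 6 UMIs. With these nuclei removed, Dlx6os1 went from 152 to 8 UMIs in control and from 42 to 6 in cre libraries. Nrxn3 went from 3393 to 1011 and from 1424 to 598. The removed nuclei were 17.8% of the class in P31 control and 14.2% in P31 cre mice, and 30.4% and 20.5% at P192. Most UMIs of these 2 genes thus lay in a minor part of the class. Under the refit's own low-count filter Dlx6os1 was not tested and only Nrxn3 of the other 3 was called. These 3 kept 0.772 (-1.31 to -1.01), just past the bound of 0.75 against it, but few UMIs per nucleus leave such nuclei undetected, so this explanation stays open. In microglia-like nuclei, where Dlx6os1 was not tested, and mature oligodendrocyte-like nuclei the mean over these genes was -0.60, or 0.411 of that in neuroblasts, so free RNA of inhibitory neurons may account for a part and cannot be told apart from a change within the neuroblasts. An effect of neuronal BACE1 loss stays among the open explanations, as a hypothesis.

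Neuronal and synaptic genes were lower in cre glia, for 78 of 91 genes in microglia-like, 88 of 110 in mature oligodendrocyte-like, 85 of 105 in astrocyte-like and 75 of 106 in precursor-like nuclei, none of them called by edgeR. The mean log2 difference was -0.41 in the 2 pairs whose control library was rich in low-UMI nuclei and -0.01 in the other 2. This ratio of 0.0343 is what debris in those 2 control libraries would give. The -0.01 averages -0.09 in the P192 females and 0.06 in the P31 males. In precursor-like nuclei the 2 means were -0.15 and -0.06, and in astrocyte-like nuclei -0.42 and -0.07. Mature myelin genes in microglia-like nuclei were at -0.30 against -0.32 for the neuronal genes, a ratio of 0.942, which is consistent with more free RNA of all sources in the controls. In precursor-like and astrocyte-like nuclei the neuronal and synaptic genes were lower in 4 of 4 pairs, so a change within these nuclei stays open.

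Cholesterol biosynthesis genes fell with age in mature oligodendrocyte-like nuclei, with a median of -1.27 log2, and without the nuclei holding a UMI of 1 of 7 young oligodendrocyte genes the median was -1.13, or 0.884 of its size, with 16 of 22 genes still called lower. Of newly formed oligodendrocyte-like nuclei at P31 98.8% held such a UMI, but that class was named from newly formed markers. Within the mature class at P31 the share was 58.6% in cluster_8, 20.6% in cluster_1 and 70.2% in cluster_19. At P192 it was 48.4%, 18.3% and 62.8%, although cluster_19 lay mostly at P192. The median nucleus of these clusters held 2584, 1575 and 2420 UMIs. Such a UMI thus did not single out younger cells, and was rarest where nuclei held the fewest UMIs. The removal took out nuclei with such a UMI whatever their age, so it argues only against these nuclei as the whole cause. Younger cells without one stay open. Within cluster_1 and within cluster_8, which held most of the class at P192 and at P31, the median was -0.52 and -0.83, on average 0.525 of that of the same genes in the class, between the bounds set for and against a shift of the class between clusters, which therefore cannot be told apart from a change within mature cells. In microglia-like nuclei the list had 0.237 of the fold (median -0.30), which argues against free RNA as the whole cause, and the age of the mice stays among the open explanations, as untested.

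Splits of the 8 libraries into 4 and 4, of which 33 could be fitted with the real one counted, were set beside the genotype and age calls. For genotype, chance could not be excluded for the 10 calls over all classes (highest other split 657), the 4 in neuroblasts (9), the 3 in precursors (23) or the 93 called tests of gene lists (124). The 2 splits with 657 calls are the same fit beside age and sex. They set the P192 male control and the P31 female control, the 2 libraries rich in low-UMI nuclei, on one side. Their cre counterparts lay on the other side, and the other 2 pairs were not divided. This fit therefore cannot tell a structure of the samples apart from a genotype effect in those 2 pairs. For age, the real split gave the most calls over all classes, 6925 against at most 121 in another split. The same held for mature oligodendrocytes (3665, highest other split 0), DG granule neurons (1874, 0), CA1 (332, 1) and astrocytes (242, 3). It also held for precursors (207, 6), microglia (147, 26), neuroblasts (60, 3) and shares (4, 1). For the 103 called tests of gene lists by age, another split gave 104. The other splits were fitted with sex and genotype but without age. The age difference therefore stayed in their spread, which lowers their counts, so they do not exclude chance. Nor can they tell age apart from a day or batch effect.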

How the results depend on the processing

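Chosen only after the result was seen were the fits without the 2 pairs whose control library was rich in low-UMI nuclei, the totals without the low-UMI cluster, the minimum of 5 nuclei, the neuroblasts without precursor nuclei, the mature oligodendrocytes of cluster_1 and of cluster_8 alone and the summed neuronal classes.

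The alternatives were set beside 24 summary results and 120 single gene results. In the fit without the 2 pairs, all P192 libraries were female and all P31 libraries male. Its age counts therefore cannot be told apart from sex. That fit held 1 library of each age and genotype, so its genotype calls, and calls lost in it, carry little weight. Of the 6925 age calls, 4228 were shared with the DESeq2 Wald test, 3878 with the fit without 2 pairs and 4277 to 5573 with each fit without 1 library. Of the 10 genotype calls, 2 were shared with the DESeq2 Wald test, 5 with no sex term, 2 without the 2 pairs (Il1rapl2 in neuroblasts and Tafa1 in macrophages) and 5 to 9 with 1 library left out. DESeq2 size factors and a clustering resolution of 0.5 shared all 10. The neuroblast, newly formed and mature oligodendrocyte shares by age kept their direction and call under every alternative run on shares. Thinning each class to its smallest library kept 7 of the 10 genotype calls and 1 of 4 in neuroblasts.

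With the DESeq2 Wald test the genotype count went from 10 to 52, P31 from 9 to 42, the difference between ages from 10 to 18, age from 6925 to 4366, neuroblasts by genotype from 4 to 0, and age calls from 3665 to 2347 in mature oligodendrocytes and from 1874 to 1167 in DG granule neurons. With no low-count filter the counts were 679 for genotype, 473 at P31, 429 at P192 (from 35), 408 between ages, 309 between sexes (from 5) and 7 in neuroblasts. The genotype count was 5 with no sex term, 181 with doublets kept, 155 with all deposited barcodes (7 in neuroblasts), 62 at resolution 2 and 25 when thinned (1 in neuroblasts). Without the 2 pairs it was 194, with 2 in neuroblasts, and the DG age count was 797. List calls with an estimated correlation were 0 by genotype and 0 by age, and with fry 1 and 21, from 93 and 103. With the 4 pairs as a replicate block the genotype count was 109, in pairs that share age and sex but not an animal.

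In mature oligodendrocytes the age count was 270 within cluster_1 alone and 107 within cluster_8 alone, and the genotype count was 37 and 0, from 0. Within cluster_8 the age directions of Man1a (0.12 log2) and Kank1 (0.25 log2) reversed.

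Leaving out 1 library gave 12 to 493 genotype calls (493 without P192 control replicate 2, 349 without P31 control replicate 2), 4 to 542 at P31, 52 to 314 at P192, 13 to 201 between ages, 2 to 260 between sexes and 1 to 13 in neuroblasts. It gave 4601 to 6796 age calls, 1116 to 1858 in DG granule neurons, and 3 to 8 of the shares by age. The astrocyte share by age ranged from -1.04 to -0.81 log2 and missed the threshold without P192 control replicate 2. Directions reversed for Thy1 in CA1 (-0.010 to 0.23 log2), CA3 (-0.019 to 0.085) and subiculum (-0.056 to 0.13), Bace1 in mature oligodendrocytes (-0.13 to 0.042), and Gm12160 by sex in CA3 (-0.43 to 9.17), mature oligodendrocytes (-0.43 to 10.51) and precursors (-0.23 to 8.28). The log2 ratio of newly formed to mature oligodendrocytes by genotype reversed too (-0.47 to 0.18), and that of neuroblasts to granule neurons ranged from 0.15 to 0.52. For all of these changes the cause was not tested.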

Other observations

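The newly formed oligodendrocyte results with a minimum of 5 nuclei were chosen only after the data were seen, and the rest of these values come from the planned tests.

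Newly formed oligodendrocyte-like nuclei, which had too few nuclei for the planned minimum, gave 13 genes with age, all lower at P192. The smallest adjusted p were those of Carmil1, a regulator of actin capping (-2.73 log2, SE 0.37, adjusted p = 0.00363), and Mobp, a myelin protein gene (-2.67 log2, SE 0.38, adjusted p = 0.00422), followed by Pdzrn3 (-3.34 log2) and Fam107b (-3.10 log2). Oligodendrocyte precursor-like nuclei lowered 1 of 18 cholesterol biosynthesis genes with age, Cyp51 by 0.57 log2 (list median -0.34, adjusted p = 0.000229, but 0.693 with an estimated correlation), and Megf11 was the 1 of 15 precursor genes that rose, by 0.39 log2.

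In microglia-like nuclei disease-associated genes fell with age in 2 of 11 over all genes and 7 adjusted over the list alone (median -0.46, adjusted p = 0.69 with an estimated correlation), the lipoprotein gene Apoe by 0.58 log2 and the lipase Lpl by 2.09 log2. Astrocyte-like nuclei raised 2 of 10 reactive astrocyte genes with age, complement C4b by 1.06 log2 and Ggta1 by 1.19 log2 (list adjusted p = 0.493), and 0 of 15 homeostatic astrocyte genes passed. Immature granule neuron genes fell there in 2 of 10 over all genes and 4 adjusted over the list alone (median -0.67, adjusted p = 0.0955 with an estimated correlation), Igfbpl1 by 5.55 and Dpysl3 by 1.05 log2, while the neuroblast-like share of nuclei fell from 5.78% to 0.454%. In CA1 mature myelin genes rose in 6 of 21 over all genes and 14 adjusted over the list alone (median 0.62, adjusted p = 0.38 with an estimated correlation), while the mature oligodendrocyte-like share rose from 8.80% to 22.6%. In neuroblast-like nuclei 0 of 18 immature granule neuron genes passed with age in edgeR (list adjusted p = 0.934), and GABA receptors and transporters fell in 2 of 16 (median -0.36, adjusted p = 0.188 with an estimated correlation).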
